A study of Homo sapiens with 33 samples.

How the data were processed

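Small-RNA libraries were made from total RNA of HCT116 cells, an established human colon carcinoma line, and of knockout derivatives of these cells. Per the labels' protocols, RNA was extracted with TRIzol and libraries were prepared with the Illumina TruSeq Small RNA kit. The 33 libraries form 11 groups of 3, each named by genotype and, where given, by siRNA. siGL stands for the siGL2 of the series design, an siRNA against luciferase used as a control, and siTNRC6C targets TNRC6C. The labels number the samples of each group as biological replicates 1 to 3, and whether they came from separate clones is not given in the sources used here. p-values measure the spread between these samples.

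The submitters deposited 2 tables with samples as rows, 1 for mature miRNA entries (2433 entries, of which 60 had no read in any library) and 1 for hairpin entries (1915 entries). The deposited values are log10 of RPM plus 0.001, where RPM is reads per 1000000 reads of the library in that table. This unit and pseudocount were read from the values. The submitters' processing notes name DESeq2 and the genome build GRCh37. The aligner, the counting rule, tool versions and read filters are not given in the sources used here.

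RPM were obtained by undoing the log10 of the deposited values. In each library these were whole multiples of what 1 read is worth for 100% of entries, at a tolerance of 0.05 reads, so whole reads and the table totals were recovered. A table total counts reads assigned to its entries. The total number of sequenced reads is unknown. Reads are not independent molecules, and floors of 3 reads per library cover counting error only. Among entries with at least 100 reads, 15 sets of mature entries (32 entries) and 29 sets of hairpins (72 entries) held identical reads in every library. Their reads cannot be told apart, so these entries are reported as uncertain.

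The main test used limma, version 3.58.1, in R 4.3.3. For each table, log2 of RPM plus 0.001 was fitted with 1 mean per group over all 33 libraries, which left 22 residual degrees of freedom. Contrasts between groups were moderated with an intensity trend and adjusted by the Benjamini-Hochberg method within each comparison. An entry was tested when it reached 10 RPM in at least 3 libraries, which kept 739 mature entries and 1307 hairpins, and it was called changed at an adjusted p under 0.05. All 11 groups enter each fit, so the DROSHA libraries, which differ most from the rest, add to the shared estimate of spread. A fold printed here is the ratio of mean RPM, and a log2 difference comes from the fit and depends on the pseudocount for entries with few reads. For arm ratios, the log2 ratio of the less to the more abundant arm was tested the same way for 168 precursors with both arms kept.

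There were 16 comparisons of mature entries: 6 main comparisons of a knockout with untreated WT cells, and 10 others within the AGO series and the siRNA-treated groups, 2 of these being interactions. Hairpins and arm ratios are reported for the 6 main comparisons. Before the data were examined, 22 lists of entries were fixed: 11 miRNA families or clusters, 8 classes by biogenesis or genomic origin, and 3 sets of miRNAs of other cell types. The 19 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, in the 6 main comparisons and in the TNRC6A/B KO cells with siTNRC6C against WT cells with siGL. Each list test was repeated with an estimated correlation. camera sets a list against the other entries, whereas limma's fry, run as a second test, asks whether the members of a list move on balance in 1 direction and compares them with no other entry. The lists overlap: miR-451a stands in 2 of them, and miR-29b-3p, miR-503-5p and miR-424-5p each stand in a family list and among the target-directed decay substrates.

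Entries named in the text followed a rule fixed before the data were examined. For each main comparison, the rule took called mature entries whose groups did not overlap and whose mean reached 100 RPM in the higher group: the 8 largest rises, the 8 largest falls, and the 8 entries most abundant in WT. Other comparisons contributed 3 rises and 3 falls, as did hairpins and arm ratios of main comparisons, where a named arm ratio needed both arms at 10 RPM in the mean of 1 group. Members of the fixed lists were named as examples.

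Alternatives were no filter, a filter of 100 RPM, pseudocounts of 10 and 0.25, centring each library on its median entry, fits with only the compared groups, the replicate number as a block, no intensity trend, and leaving out each library in turn. Others were chosen after the data were seen: voom from limma on the recovered reads, leaving out the DROSHA libraries, and leaving out TNRC6A/B KO replicates 1 and 2 together, which leaves 1 library of that group. Tests on counts such as DESeq2 were not run here.

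The method was tested on simulated reads drawn from the real means, library sizes and spreads, with 200 entries between 10 and 5000 RPM changed 1.5-fold, 2-fold or 4-fold and the 8 most abundant entries taking up the change so that totals stayed. For AGO1/2/3 KO against WT, 68.1%, 87.1% and 93.1% of the entries changed by these folds were called in the right direction, over 514 tested entries. For AGO1 KO the shares were 70%, 84.9% and 97% over 509 entries. For TNRC6A/B KO they were 66.7%, 87.5% and 96.1% over 515 entries. At the depth of the DROSHA libraries they were 70.6%, 91.1% and 100% over 513 entries, but 12.8% of unchanged entries were called there, against 0.651% to 0.98% in the other simulated comparisons. Fewer entries were tested in each simulation than in the reported fits, so the simulated libraries did not reproduce all real groups. The shares thus hold for the simulated fits and do not give the power of the reported tests. Where the total shifts, RPM values of unchanged entries shift with it.

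Positions of hairpins were taken from GENCODE release 29 on GRCh38, in which 19 of 20 hairpins looked up were found by symbol. They are unrelated to the GRCh37 build of the submitters' notes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.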

Results

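Small RNAs were sequenced from HCT116 colon carcinoma cells and from derivatives lacking proteins of the RNA interference machinery. The 11 groups, of 3 libraries each, were untreated wild type (WT), the knockouts (KO) of DROSHA, AGO1, AGO2, AGO1 with AGO2, AGO1 with AGO2 and AGO3, and TNRC6A with TNRC6B, and WT and TNRC6A/B KO cells given a control siRNA (siGL) or an siRNA against TNRC6C (siTNRC6C). The question was what the loss of these factors does to the miRNA profile. The knocked-out mRNAs are not measured by small-RNA sequencing, so the genotype labels could not be checked from the targeted genes.

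Each library held 197912 to 4444261 reads over mature entries and 83227 to 1471305 over hairpin entries. Mean mature reads per library were 2770099 ± 173545 (SD, n = 3) in WT, 2853976 in AGO1 KO, 2389085 in AGO2 KO, 2060852 in AGO1/2 KO, 1382294 ± 93650 in AGO1/2/3 KO, 3434959 ± 879522 in TNRC6A/B KO and 215102 ± 17871 in DROSHA KO. The siRNA-treated groups averaged 2278721 to 2712357. WT libraries thus held 12.9 times the mature reads of DROSHA KO libraries, and every level below is in RPM, reads per 1000000 reads of the library in that table. No 2 replicates of a group agreed within sampling noise, since the chi-square per degree of freedom over 33 pairs went from 3.36 to 448.5, the highest being TNRC6A/B KO replicates 1 and 3. In WT cells miR-100-5p led with 166100 ± 16730 RPM (SD, n = 3), followed by miR-92a-3p, miR-191-5p, miR-21-5p, miR-10a-5p, let-7a-5p, miR-99b-5p and miR-22-3p. The 10 most abundant entries took 56.2% of reads in WT, 66.7% in AGO1/2/3 KO and 88.3% in DROSHA KO.

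**Figure D1:**
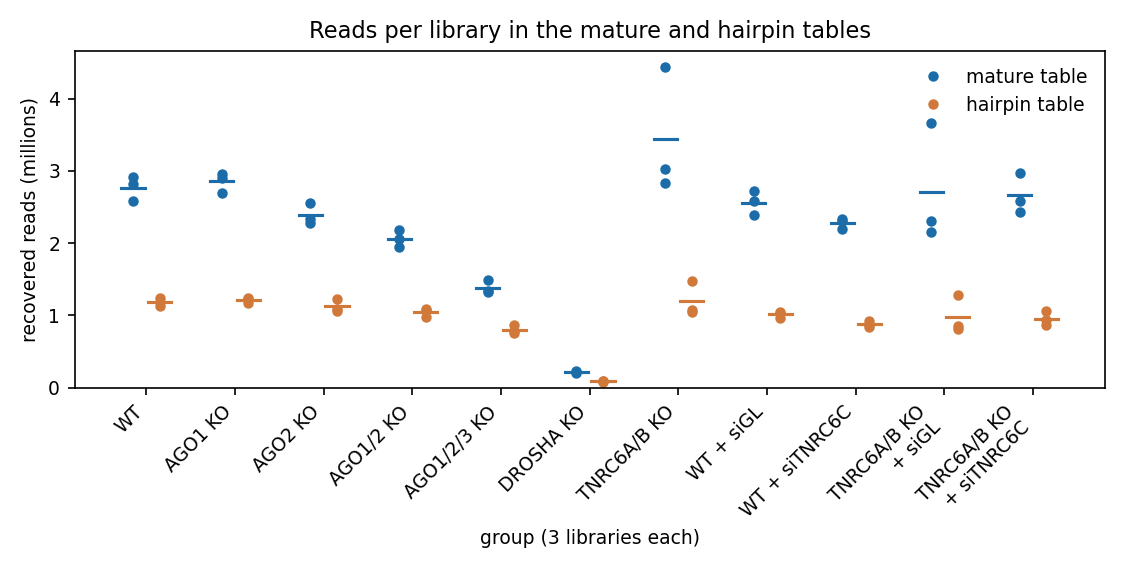
Reads per library (y axis) in the mature and hairpin tables for the 11 groups (x axis). Points are libraries and lines are group means. The 3 DROSHA KO libraries lie lowest in both tables, at a mean of 215102 mature reads.

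Loss of DROSHA, the nuclear nuclease that cuts most miRNA hairpins out of their primary transcripts, removed the leading miRNAs of HCT116 cells almost entirely. miR-100-5p fell from 166100 ± 16730 to 233 ± 117 RPM (714-fold lower, n = 3 per group). miR-92a-3p was 811-fold lower, miR-191-5p 665-fold, miR-21-5p 667-fold, let-7a-5p 803-fold, miR-99b-5p 589-fold, miR-22-3p 530-fold and miR-10a-5p 303-fold lower. Some abundant miRNAs left no read in any DROSHA KO library. Against a floor of 3 reads per library, miR-200c-3p (4275 ± 106 in WT) was at least 305-fold lower, miR-15a-5p at least 86.2-fold, miR-148b-3p at least 77.8-fold, miR-331-3p at least 66.9-fold, miR-197-3p at least 66.8-fold, miR-15b-5p at least 65.5-fold, miR-19b-3p at least 63.8-fold and miR-29b-3p at least 61.4-fold lower. In their place miR-1260a, miR-1260b, miR-7977 and miR-484 took 217700, 193700, 161700 and 117500 RPM.

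Mirtrons, whose hairpins are spliced introns that do not need DROSHA, rose together: all 12 tested entries passed the test. Among them miR-1228-3p, miR-1233-3p and miR-1227-3p had 0 reads over the WT libraries, miR-1236-3p and miR-1228-5p had 1, and miR-1237-3p had 3. These could not pass the filter in WT and were let in by other groups, so their calls were partly fixed by the filter. The sum of all 23 mirtron entries with a read went from 114 ± 21.6 to 7692 ± 959 RPM, 67.5-fold higher; list sums here and below cover every member with a read, tested or not. miR-1226-3p, from an intron of DHX30 (GRCh38 chromosome 3, 47849555 to 47849629), rose from 29.8 ± 5.15 to 4274 ± 767 RPM. miR-1229-3p rose from 4.34 ± 0.391 to 949 ± 63.9, and miR-877-5p, from an intron of ABCF1 (chromosome 6, 30584332 to 30584417), from 67.5 ± 11.2 to 1466 ± 100. The miR-320 family and miR-484, whose short hairpins are known to be transcribed directly, rose in 5 of 6 entries and were 47.5-fold higher in sum. miR-484 went from 2053 ± 212 to 117500 ± 11400 and miR-320a-3p from 1736 ± 7.40 to 71040 ± 3467. miR-320 members have near-identical sequences, so reads may be split between them. Entries that overlap snoRNAs rose in 6 of 7, with miR-664a-3p going from 10.6 ± 3.75 to 983 ± 23.0. Entries that resemble tRNA, rRNA or snRNA rose in 6 of 10 (5 adjusted over the list alone) and fell in 1, miR-10396b-3p. Their sum was 53.3-fold higher. Their median log2 difference was 2.91, whereas the smaller DROSHA KO total alone would give an unchanged entry 3.69. At the median no rise beyond scaling was shown for this list.

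Every tested member of the conserved families fell in DROSHA KO cells. These were 19 of 19 let-7 entries (the sum of all 20 with a read was 693-fold lower), 20 of 20 of miR-17/92 and its paralogues, 9 of 9 miR-200, 12 of 12 miR-15/16, 10 of 10 miR-23/27/24, 16 of 16 miR-29 and miR-30, 8 of 8 miR-181, 13 of 13 of the miR-10, miR-99, miR-100 and miR-125 families, 8 of 8 of the miR-21, miR-31, miR-155, miR-221 and miR-222 list, 4 of 4 of the miR-183 cluster and 5 of 5 p53-induced miRNAs. The 14q32 imprinted cluster (8 of 8), the target-directed decay substrates (5 of 5), the blood cell miRNAs (4 of 4) and the stromal and endothelial miRNAs (8 of 8) also fell member by member. Adjusted over the list alone, counts were the same except where given. Of the largest single rises, miR-3929 went from 1.57 ± 0.899 to 1004 ± 176 RPM, miR-10399-3p from 3.63 ± 0.595 to 901 ± 124 (log2 difference 7.96 ± 0.35 SE, adjusted p = 6.7e-17), miR-6858-3p from 0.476 to 262 and miR-6789-3p from 1.12 to 221.8. miR-4709-5p, miR-3620-3p, miR-7114-3p and miR-6871-3p reached 150.5, 121, 108 and 135 RPM against 1, 2, 2 and 3 WT reads.

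limma called 700 of 739 mature entries in DROSHA KO cells, 234 higher and 466 lower, and camera called 15 of 19 lists against the other entries. A mature read was worth 4.28 to 5.05 RPM in these libraries. Few reads thus met the filter there, and the 234 include entries let in by DROSHA KO reads. The adjusted p of camera was 0.000507 for mirtrons and 0.0193 with an estimated correlation, so that call held, though mirtrons with 0 to 3 WT reads enter it. The rises of the miR-320 and miR-484 list (0.000494), the snoRNA-overlapping entries (0.00773) and the tRNA-like entries (0.00183) did not hold: their adjusted p = 0.0617, 0.0519 and 0.119 with an estimated correlation. The falls were called at an adjusted p of 0.00656 for let-7 and for miR-29 and miR-30, 0.00183 for miR-17/92, 0.0123 for miR-181, 0.0163 for the miR-10, miR-99, miR-100 and miR-125 families, 0.0187 for miR-15/16, 0.0247 for the miR-21 list, 0.0293 for miR-200, 0.0333 for the stromal list, 0.0453 for the p53-induced list and 0.0455 for miR-23/27/24. None of these 11 held, with adjusted p = 0.0570 (miR-29 and miR-30) to 0.305 (miR-200) with an estimated correlation. The falls of the miR-183 cluster (0.191), 14q32 cluster (0.650), decay substrates (0.109) and blood list (0.559) were not called against the other entries, whose median log2 difference was itself -9.83. Without DROSHA KO replicate 2 the p53-induced and stromal lists had an adjusted p of 0.0721 and 0.0574, and without replicate 3 they had 0.0725 and 0.0569 and miR-23/27/24 had 0.0766.

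**Figure D2:**
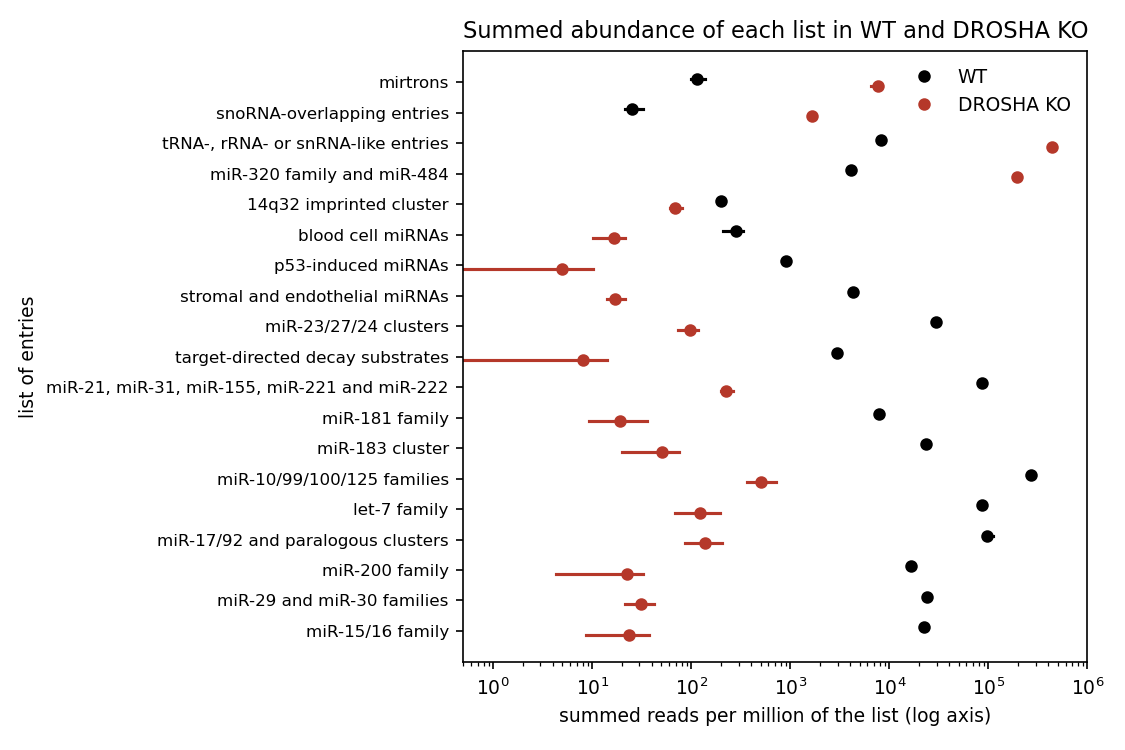
Summed RPM (x axis, log scale) of each list with at least 3 tested members (y axis) in WT and DROSHA KO cells. Points are means of 3 libraries and lines run from the lowest to the highest library, reaching the left edge where a library had 0 reads. Mirtrons, snoRNA-overlapping entries, tRNA-like entries and the miR-320 and miR-484 list lie higher in DROSHA KO, by 47.5-fold to 67.5-fold, and the other lists lie lower.

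Among hairpins, mir-16-2 (3519 ± 67.4 in WT), let-7f-2 and mir-16-1 had no read in DROSHA KO and were at least 103-fold, 99.1-fold and 78.0-fold lower, while mir-6815 rose from 1.07 ± 1.86 to 334 ± 66.7 RPM. mir-7114 stood at 253 ± 63.4 against 3 WT reads. mir-6895, at 341 ± 99.7 against 1.98, was called as well, but not without WT replicate 2 (adjusted p 0.103) or with median centring (0.0616). limma called 771 of 1307 hairpins, 486 higher and 285 lower. With each library centred on its median the split was 199 higher and 374 lower, because the median hairpin shifted from 3.62 to 0.85 on the log2 scale. The same centring moved the median of mature entries from -9.83 to -7.68, with 265 higher and 442 lower. Of 168 arm ratios 81 changed. The minor arm gained on the major arm for miR-574, where miR-574-3p went from 421 to 2.85 RPM and miR-574-5p from 140 to 46.8. This gain, those of miR-1296-3p and miR-26b-3p and the drops of miR-3613-5p, miR-181a-3p and miR-130b-5p against their other arm each rested on an arm with 0 reads in at least 1 DROSHA KO library. In a fit of only the compared groups the calls of miR-574, miR-1296, miR-26b and miR-3613 were lost (adjusted p 0.12, 0.111, 0.175 and 0.0572). With a pseudocount of 10 the ratios of miR-181a and miR-130b turned from falls (-9.98 for miR-130b, -10.41 for miR-181a on the log2 scale) to rises (2.06 and 2.09).

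AGO proteins hold mature miRNAs in the silencing complex. Loss of AGO1 alone changed few entries, led by miR-34a-5p, a p53-induced miRNA, which rose from 161 ± 11.2 to 420 ± 18.0 RPM (2.61-fold, log2 difference 1.39 ± 0.17 SE, adjusted p = 5.4e-06, n = 3 per group). Its other arm miR-34a-3p rose from 24.2 ± 2.03 to 50.9 ± 5.39, and miR-15a-5p rose from 1208 ± 30.9 to 1648 ± 43.2. miR-99b-3p fell from 115 ± 6.15 to 50.9 ± 1.79 (2.26-fold lower), miR-7706 from 183 ± 12.6 to 87.3 ± 13.1 and miR-199b-5p from 122 ± 16.8 to 62.1 ± 4.08. The 8 entries most abundant in WT were not called, among them miR-100-5p at 171000 ± 6616 and miR-99b-5p at 24380 ± 466 (adjusted p 0.132). In a fit of only the compared groups miR-99b-5p (0.00145), miR-191-5p (0.0189) and miR-21-5p (0.0246) were called, and without the DROSHA KO libraries miR-99b-5p (0.000766) and miR-191-5p (0.0143). The hairpins mir-3615 (517 ± 98.5 to 191 ± 16.6), mir-584 (327 to 127) and mir-877 (1507 to 722) fell.

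Of the lists, the p53-induced miRNAs rose (2 of 5 members, 3 adjusted over the list alone; camera adjusted p = 4.99e-05, and adjusted p = 0.0218 with an estimated correlation). The list members miR-34a-5p and miR-34a-3p are 2 arms of 1 hairpin, so this call rests in part on 1 locus. The miR-320 and miR-484 list fell (1 of 6, miR-320c, and 5 adjusted over the list alone; 2.37e-05, and 0.0471 with an estimated correlation). Called at the preset correlation were also a rise of the miR-15/16 family (2 of 12; 0.0011), a rise of the 14q32 cluster (0 of 8, 1 adjusted over the list alone; 0.0147) and a fall of the stromal list (1 of 8, 4 adjusted over the list alone; 0.0134). These 3 did not hold, with adjusted p = 0.0929, 0.0929 and 0.143 with an estimated correlation. Across all comparisons the list calls that held with an estimated correlation were the mirtrons in DROSHA KO and the p53-induced and miR-320 and miR-484 lists in AGO1 KO.

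limma called 29 of 739 mature entries in AGO1 KO, 9 higher and 20 lower, 4 of 1307 hairpins, all lower, and 0 of 168 arm ratios, where 6 had an unadjusted p under 0.05 and a pseudocount of 10 gave 9 calls. The calls of let-7i-3p, miR-12136, miR-30e-5p, miR-148a-5p and miR-1301-3p (adjusted p 0.0413 to 0.0483) were each lost without any 1 of the 6 libraries (0.051 to 0.241), and that of miR-199b-5p without WT replicates 1 or 2 or AGO1 KO replicate 2 (0.0612 to 0.0767). The list calls of the 14q32 cluster and the stromal list were lost without WT replicate 3 (0.0541) and WT replicate 2 (0.0641). The call of miR-15a-5p was lost with no filter (0.145). Median centring ended all 4 hairpin calls, and that of mir-584 was also lost without WT replicates 1 (0.0553) or 3 (0.0936) or AGO1 KO replicate 3 (0.0870). The number of mature calls went from 11, without WT replicate 1, to 127 when the fit held only the compared groups.

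Loss of AGO2, the AGO protein able to slice its targets, raised several passenger strands. miR-21-3p rose from 14660 ± 298 to 35010 ± 2146 RPM (2.39-fold, adjusted p = 0.00094, n = 3 per group), miR-25-5p from 45.5 ± 6.25 to 145 ± 12.6, miR-18a-3p from 114 ± 30.6 to 248 ± 19.5, and miR-181a-2-3p from 154 ± 8.79 to 308 ± 9.50. miR-210-5p and miR-16-2-3p rose 2.29-fold and 2.14-fold. The entries miR-642a-3p and miR-642b-5p, which hold identical reads and so cannot be told apart, rose from 18.0 ± 4.21 to 108 ± 8.94. miR-181c-5p fell from 148 ± 8.55 to 20.3 ± 1.89 (7.30-fold lower, log2 difference -2.87 ± 0.13 SE), miR-652-3p from 141 ± 6.59 to 31.1 ± 2.70, let-7c-5p from 122 ± 5.85 to 38.4 ± 4.63, miR-33b-5p from 342 ± 51.8 to 122 ± 8.83, and miR-32-5p, miR-153-3p, miR-30e-5p and miR-1301-3p by 2.19-fold to 3.02-fold. Of the 8 entries most abundant in WT, miR-99b-5p fell, from 35250 ± 941 to 22060 ± 1569, a call lost without WT replicate 1 (adjusted p 0.0543), without AGO2 KO replicate 1 (0.0667), with median centring (0.0573) or with no filter (0.0524).

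limma called 95 mature entries in AGO2 KO, 27 higher and 68 lower; centring on the median gave 45 higher and 52 lower and moved the median of all entries from -0.22 to -0.09. Among the let-7 family 3 of 19 rose and 1 fell, and in the miR-181 family 2 of 8 rose and 2 fell (3 adjusted over the list alone), with camera adjusted p = 0.4155 and 0.7785. camera called 0 of 19 lists, with 2 at an unadjusted p under 0.05, and 0 with an estimated correlation. limma's fry, which asks whether a list moves on balance 1 way and not whether it moves more than the other entries, called 3. Hairpins mir-181a-1 and mir-181a-2, which share most of their reads, rose from 2065 ± 95.4 and 2057 to 4134 ± 246 and 4099, mir-548f-1 rose from 12.1 to 111, and mir-532, mir-301a and mir-98 were 4.47-fold, 4.40-fold and 4.07-fold lower, among 4 higher and 25 lower hairpins. In 22 of 168 precursors the arm ratio changed, 17 towards the minor arm: miR-32 went from 0.392 to 1.75 and miR-18a from 0.199 to 0.663 minor reads per major read, while miR-30e went from 0.205 to 0.0483. Without a filter 5 arm ratios were called, that of miR-18a no longer (adjusted p 0.110), and in a fit of only the compared groups 257 mature entries were.

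When AGO1 and AGO2 were both lost, several passenger strands rose, and the leading miRNAs changed in both directions. miR-21-3p reached 108000 ± 36620 RPM, 7.37-fold its WT level, and its ratio to miR-21-5p went from 0.276 to 2.44. miR-25-5p rose 11.4-fold to 520 ± 111, miR-22-5p 11-fold to 276 ± 66.2, miR-629-3p 8.33-fold, miR-16-2-3p 7.82-fold, let-7b-3p from 263 ± 20.4 to 1696 ± 102, and the shared reads of miR-642a-3p and miR-642b-5p 17.9-fold to 322 ± 60.7. miR-18a-3p and miR-181a-2-3p, at 172 ± 25.7 and 295 ± 51.5, did not exceed their AGO2 KO levels of 248 and 308. Of the leading miRNAs, miR-22-3p rose from 32530 ± 5739 to 86620 ± 9784 and miR-10a-5p from 46830 ± 3064 to 69890 ± 7258, whereas miR-100-5p fell to 71640 ± 6734 (2.32-fold lower) and miR-99b-5p to 9259 ± 183 (3.81-fold lower). miR-141-3p, of the epithelial miR-200 family, fell from 6245 ± 446 to 1381 ± 27.1, miR-652-3p was 9.32-fold lower, miR-181c-5p 6.23-fold, miR-1301-3p 4.42-fold, miR-454-3p 4.32-fold and miR-148b-3p 4.18-fold lower. miR-10396b-3p and miR-4634 were 9.93-fold and 8.74-fold lower; both also differed 69.2-fold or more between WT groups with and without siGL.

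limma called 243 mature entries in AGO1/2 KO, 95 higher and 148 lower, with 30 hairpins higher and 95 lower, and 47 arm ratios (37 towards the minor arm). In the let-7 family 5 of 19 rose, 4 of them -3p entries beside let-7b-3p, and 1 fell; in the miR-320 and miR-484 list 4 of 6 fell and in the stromal list 5 of 8, with camera adjusted p = 0.1105, 0.1105 and 0.123. It called 0 of 19 lists, with 5 at an unadjusted p under 0.05, and 0 with an estimated correlation. By fry, which makes no comparison with the other entries, 9 lists were called. Hairpins mir-561 and the identical mir-3158-1 and mir-3158-2 rose (54.5 to 242, and 239 to 1133 ± 566), and mir-4741, mir-3195 and mir-4634 fell, the call of mir-3195 being lost without AGO1/2 KO replicate 1 (adjusted p 0.0661), without WT replicate 1 (0.0504) and in a fit of only the compared groups (0.248), as was that of mir-4634 (0.12). These 3 hairpins also stood low in WT cells given siGL, with no AGO loss, at 16.05, 129 and 18.7 RPM against 531, 12150 and 1203 in WT. Arm ratios of miR-25 and miR-15a rose 3.74 and 3.73 on the log2 scale, and those of miR-33b and miR-30e fell by 2.85 and 2.54. The call of miR-10a-5p was lost without WT replicate 3 (adjusted p 0.0865), without AGO1/2 KO replicates 1 (0.0739) or 3 (0.0808), with no filter (0.0663) and with median centring (0.0838). A filter of 100 RPM left 153 mature calls, and voom gave 405.

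Loss of AGO1, AGO2 and AGO3 together gave the largest changes of the AGO series. miR-21-3p rose 14.4-fold to 211700 ± 10020 RPM and became the most abundant entry, and miR-22-3p rose 4.77-fold to 155200 ± 7824. miR-25-5p rose from 45.5 ± 6.25 to 1980 ± 123 (43.5-fold, log2 difference 5.45 ± 0.31 SE, adjusted p = 3.2e-13), miR-27b-5p 18.3-fold to 1579 ± 192, miR-22-5p 20.9-fold to 525 ± 25.1, miR-142-5p 13.9-fold to 620 ± 62.2 and miR-4661-3p 14.7-fold to 119 ± 3.39. miR-100-5p fell to 23060 ± 5676 (7.20-fold lower), miR-99b-5p to 4781 ± 779 (7.37-fold), miR-191-5p to 21860 ± 777 (3.06-fold) and miR-92a-3p to 32240 ± 2732 (2.15-fold). The guide strands miR-21-5p (63960 ± 1737) and let-7a-5p (33720 ± 716) were not called, with an adjusted p of 0.111 and 0.86 by limma, though miR-21-5p was called in a fit of only the compared groups (0.00879) and by voom (0.0433).

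The miR-200c and miR-141 pair, on chromosome 12 (GRCh38, mir-200c at 6963699 to 6963766 and mir-141 at 6964097 to 6964191), nearly disappeared in AGO1/2/3 KO cells. miR-141-3p fell from 6245 ± 446 to 77.8 ± 19.2 RPM (80.3-fold lower) and miR-200c-3p from 4275 ± 106 to 138 ± 39.5 (31.0-fold lower), and hairpins mir-200c and mir-141 fell from 1445 ± 81.9 to 8.45 ± 5.55 and from 6062 ± 676 to 72.2 ± 10.6. In the miR-200 family as a whole 5 of 9 fell and miR-200a-5p rose (camera adjusted p = 0.1097), and its sum went from 16400 ± 138 to 1669 ± 253. miR-301b-3p was 53.9-fold lower, miR-301a-3p 38.4-fold, miR-1301-3p 15.8-fold, miR-143-3p 12.9-fold and miR-199b-5p 12.8-fold lower. miR-30a-3p (307 ± 39.8 against 11.4), miR-486-3p (285 ± 57.4 against 11.6) and miR-141-5p (42.0 ± 8.30 against 1168) were called at an adjusted p of 0.0368 to 0.046, each lost without any 1 of the 6 libraries (0.0666 to 0.0986). Their levels did not overlap between the groups, with miR-141-5p at 35.6 to 51.4 RPM against 1163 to 1174 in WT. Spread in other groups enters these limma tests. In DROSHA KO libraries miR-141-5p ran from 0 to 10.1 RPM and miR-486-3p from 0 to 8.56.

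camera called 3 of 19 lists in AGO1/2/3 KO, each at an adjusted p of 0.0208 and each lost, with adjusted p = 0.249 with an estimated correlation. The miR-23/27/24 clusters were called up, with 4 of 10 members risen, all passenger -5p strands (miR-23a-5p, miR-23b-5p, miR-27a-5p and miR-27b-5p); their median log2 difference was -0.07 while their mean was 1.22. The miR-320 and miR-484 list was called down (4 of 6 fell, miR-320a-3p from 1736 ± 7.40 to 784 ± 29.6), but not with median centring (0.052). The stromal and endothelial list was called down (5 of 8 fell, miR-126-3p from 529 ± 11.5 to 165 ± 11.5). Of the lists not called, the 14q32 cluster had 6 of 8 members fallen (7 adjusted over the list alone, adjusted p 0.11, and 0.0305 without AGO1/2/3 KO replicate 2), the decay substrates 3 of 5 (0.315), and the mirtrons 4 of 12 (0.505). The mirtron sum was 114 ± 21.6 RPM in WT, 68.0 ± 2.01 in AGO1 KO, 32.7 ± 2.53 in AGO2 KO, 12.6 ± 2.09 in AGO1/2 KO and 7.25 ± 2.28 in AGO1/2/3 KO, 15.7-fold lower than in WT. Of miR-17/92 and its paralogues 5 of 20 rose, led by miR-25-5p, and 8 fell, among them miR-18a-5p from 574 ± 13.5 to 56.8 ± 10.4 (adjusted p 0.505 for the list). Of the let-7 family 5 of 19 rose, each a -3p entry, and let-7c-5p fell (0.0762).

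limma called 358 mature entries in AGO1/2/3 KO, 126 higher and 232 lower, 195 hairpins (63 higher, 132 lower) and 50 arm ratios (39 towards the minor arm). Centring moved the median of all mature entries from -0.65 to -0.46. Minor to major ratios went from 0.00416 to 0.2095 for miR-25 and from 0.00544 to 0.117 for miR-27b, and miR-15a rose too, while miR-33b, miR-671 and miR-30e moved the other way. Where both arms were called, 27 of 49 precursors had both arms fallen, 8 had both risen, 9 had a minor arm risen and a major arm fallen, and 5 the opposite. Hairpins mir-3158-1 and mir-3158-2 rose together from 239 ± 29.8 to 2356 ± 323 and mir-561 from 54.5 to 469, and mir-3200 fell from 388 to 7.72, a call lost without 5 of the 6 libraries (adjusted p 0.0628 to 0.0936; WT replicates 1, 2 and 3 and AGO1/2/3 KO replicates 1 and 3). A filter of 100 RPM left 200 mature calls.

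**Figure D3:**
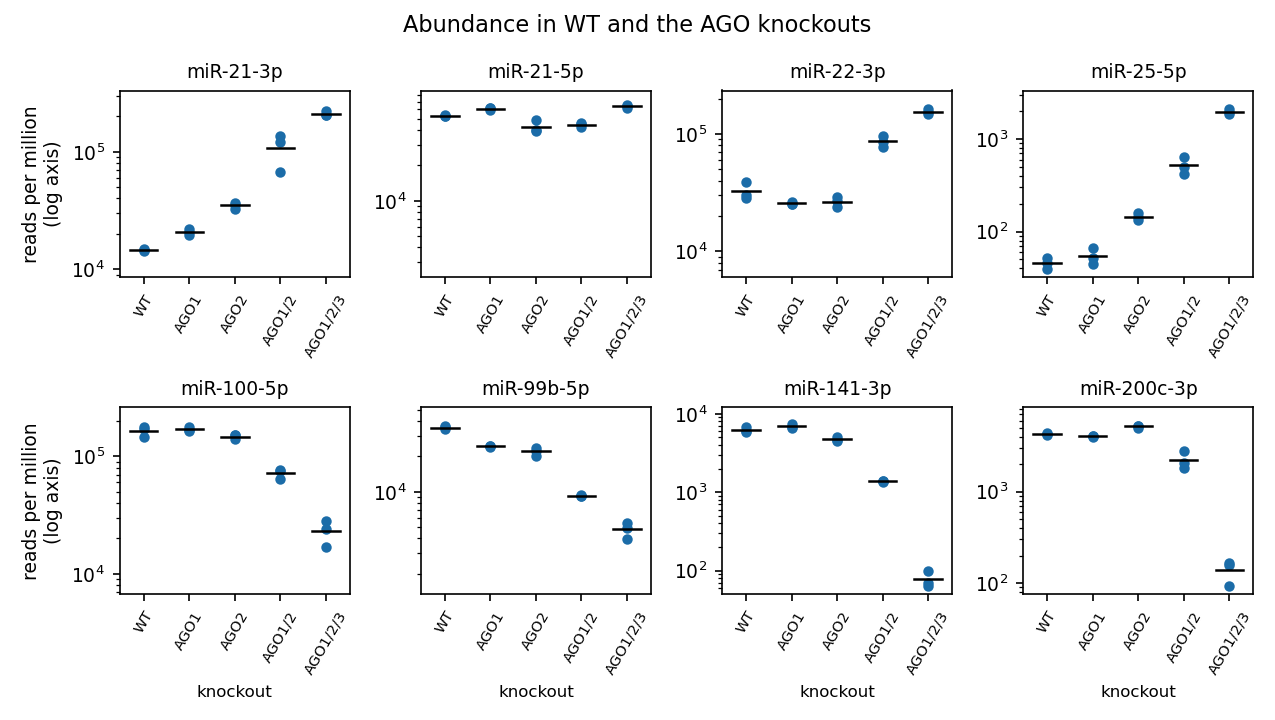
RPM (y axis, log scale) of 8 mature miRNAs in WT and the AGO knockouts (x axis). Points are libraries and lines are means of 3. miR-21-3p and miR-25-5p lie highest in AGO1/2/3 KO, at 211700 and 1980, where miR-141-3p and miR-200c-3p lie lowest, at 77.8 and 138.

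Over the 168 precursors, minor arms took 6.0% ± 0.27 of reads in WT, 6.83% ± 0.17 in AGO1 KO, 9.31% ± 0.32 in AGO2 KO, 19.2% ± 4.70 in AGO1/2 KO and 31.4% ± 0.90 in AGO1/2/3 KO. Each of these 4 knockouts had p = 0.1 against WT in a two-sided exact permutation test, the smallest that 3 libraries against 3 allow. The same exact permutation test gave p = 0.1 for lower shares in DROSHA KO (3.97%), TNRC6A/B KO (4.48%), TNRC6A/B KO with siGL (4.78%) or siTNRC6C (4.64%), and WT with siTNRC6C (5.43%), which has no knockout. Without miR-21 the shares were 4.40% in WT, 5.32% in AGO1/2 KO and 7.08% in AGO1/2/3 KO, so miR-21 carried most of the shift. AGO1 KO and AGO2 KO then stood at 4.50% and 4.85%, with p = 0.8 and 0.2 in the same exact permutation test, in which AGO1/2 KO and AGO1/2/3 KO again had p = 0.1.

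**Figure D4:**
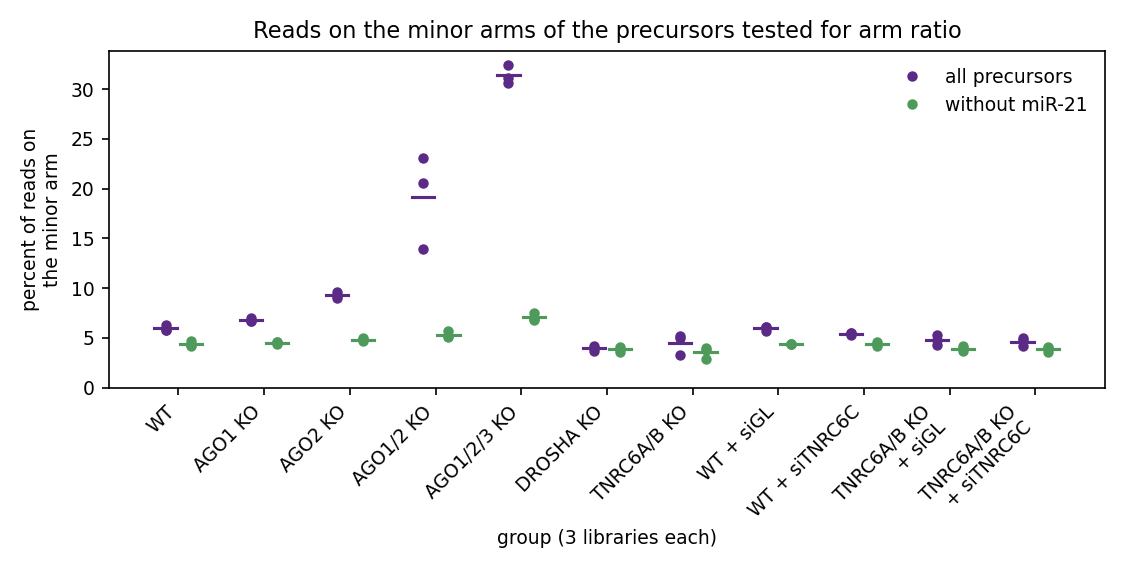
Percent of reads on the minor arm (y axis) over the precursors tested for arm ratio, with and without miR-21, in the 11 groups (x axis). Points are libraries and lines are means of 3. AGO1/2/3 KO lies highest at 31.4%, or 7.08% without miR-21.

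Within the AGO series, direct tests gave the following differences. AGO2 KO cells had more miR-18a-3p (248 ± 19.5 against 68.7 ± 5.53) and more of the shared miR-642a-3p and miR-642b-5p reads than AGO1 KO cells, and less miR-181c-5p (20.3 ± 1.89 against 158 ± 5.07), let-7c-5p and miR-654-3p, with 52 entries higher and 60 lower. From AGO2 KO to AGO1/2 KO, miR-142-5p rose from 45.9 ± 2.87 to 241 ± 80.6, miR-22-5p from 54.1 to 276 and miR-550a-5p from 54.8 to 213. miR-141-3p fell from 4768 ± 270 to 1381 ± 27.1, with 80 entries higher and 72 lower. miR-10396b-3p and miR-4634 were also called lower, but not in a limma fit of only these groups (adjusted p 0.0648 and 0.055). From AGO1/2 KO to AGO1/2/3 KO, miR-27b-5p rose from 249 ± 100 to 1579 ± 192, with 84 higher and 143 lower entries. These compare groups of knockout cells, and the labels do not tell a trait of a clone apart from the further loss. miR-30a-5p had no read in AGO1/2 KO and stood at 250.2 ± 30.1 in AGO1/2/3 KO, at least 172-fold higher, and miR-30a-3p rose from 2.59 to 307. miR-200c-5p fell from 102 ± 19.3 to 1.98 ± 1.19 and miR-141-3p from 1381 ± 27.1 to 77.8 ± 19.2. The effects of AGO1 loss with and without AGO2 differed for 67 entries by limma's interaction term, 44 higher and 23 lower, or 42 and 35 with median centring, which moved the median from 0.04 to -0.06.

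TNRC6 proteins are the scaffolds that link AGO to the silencing machinery. In TNRC6A/B KO cells miR-181a-5p rose from 6194 ± 392 to 16690 ± 4651 RPM (2.69-fold, adjusted p = 0.00035, n = 3 per group), miR-425-5p from 801 ± 48.3 to 2282 ± 200.7 (log2 difference 1.51 ± 0.10 SE, 1.2e-10), miR-143-3p from 182 ± 48.1 to 618 ± 259, miR-221-5p from 122 ± 10.9 to 363 ± 79.9, and miR-342-3p, miR-30e-5p, miR-181c-5p and miR-454-3p by 2.38-fold to 3.47-fold. miR-92a-3p fell from 69470 ± 11580 to 25870 ± 9756, 2.69-fold lower. miR-4454, a tRNA-like entry, fell from 1436 ± 327 to 77.6 ± 11.4, 18.5-fold lower. Other falls among the largest, some of them larger still, were of miR-4632-3p, miR-10396b-3p, miR-4787-5p, miR-4634, miR-4485-3p, miR-6089 and miR-6743-5p. Those entries stood at 101 to 250.5 RPM in WT and at 0.295 to 15.6 in the knockout. These 7 also stood at 0.631 to 13.1 RPM in WT cells given siGL, without the knockout.

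By list, miR-17/92 and its paralogues fell (7 of 20, 10 adjusted over the list alone; camera adjusted p = 0.00237, and adjusted p = 0.2996 with an estimated correlation), with miR-19a-3p going from 626 ± 39.9 to 312 ± 136. The p53-induced miRNAs rose (3 of 5, 4 adjusted over the list alone; 0.0034, and adjusted p = 0.0755 with an estimated correlation), with miR-34c-5p going from 5.50 ± 1.24 to 61.3 ± 12.7. The miR-181 family (4 of 8; 0.011), the miR-21, miR-31, miR-155, miR-221 and miR-222 list (3 of 8; 3 rose and 1 fell adjusted over the list alone; 0.0285) and the stromal list (5 of 8, the pair miR-199a-3p and miR-199b-3p sharing reads; 0.00357) rose, with adjusted p = 0.2996, 0.163 and 0.114 with an estimated correlation. Mirtrons were called up (3 of 12; 0.00778, and adjusted p = 0.0755 with an estimated correlation), but the 3 that rose, miR-1227-3p, miR-1228-5p and miR-1233-3p, stood at only 0.413 to 1.38 RPM. The sum of all mirtrons with a read was 298 ± 15.1 against 114 ± 21.6 RPM in WT (2.615-fold), and 298 ± 13.2 against 103 ± 13.97 with siGL, carried by more abundant members that were not called one by one. The tRNA-like entries fell (4 of 10; 5 fell and 1 rose adjusted over the list alone; 0.0127, and adjusted p = 0.2996 with an estimated correlation). Of those that fell, miR-10396b-3p stood at 1.42 ± 0.795 RPM and miR-4485-3p at 13.15 ± 0.377 in WT cells given siGL as well, and the list was not called in TNRC6A/B KO with siTNRC6C against WT with siGL (1 of 10 fell, adjusted p 0.925). Without TNRC6A/B KO replicate 3 the miR-21 list and the tRNA-like list had an adjusted p of 0.0573 and 0.0818.

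limma called 163 mature entries in TNRC6A/B KO, 58 higher and 105 lower. Centring on the median gave 93 higher and 76 lower and moved the median of all entries from -0.09 to 0.24. TNRC6A/B KO replicates 1 and 2 stood apart in the hairpin table, where 1689 and 1721 hairpins had a read in them, against 1546 in replicate 3 and 1325 to 1572 in the other 30 libraries. In mature reads replicate 3 stood furthest from its group, with a chi-square per degree of freedom of 448.5 and 407 against replicates 1 and 2, and 35.2 between these 2; without it 61 mature entries were higher and 77 lower. Leaving out replicates 1 and 2 leaves 1 knockout library, replicate 3, tested with the spread of the other groups, so a lost call there does not show a missing difference. In that fit 34 mature entries were higher and 160 lower, 120 of the 163 calls were shared, and miR-181a-5p was not called (adjusted p 0.0807). The rises of miR-21-5p and miR-22-3p among the leading miRNAs (1.36-fold and 1.43-fold) and the falls of miR-6743-5p and miR-6089 were lost without single libraries. For miR-21-5p these were WT replicates 1 (adjusted p 0.0503), 2 (0.0578) and 3 (0.0590) and TNRC6A/B KO replicate 1 (0.104), and for miR-22-3p WT replicates 1 (0.139) and 2 (0.177) and TNRC6A/B KO replicates 1 (0.0524), 2 (0.170) and 3 (0.0654). For miR-6743-5p they were WT replicates 1 (0.0696), 2 (0.0599) and 3 (0.0675) and TNRC6A/B KO replicate 2 (0.152), and for miR-6089 WT replicates 1 (0.0765), 2 (0.0683) and 3 (0.0518) and TNRC6A/B KO replicate 3 (0.214).

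Hairpins changed in both directions in TNRC6A/B KO, 56 higher and 51 lower, or 22 and 203 with median centring. mir-4772 had no read in WT and 814 ± 686 RPM in the knockout, at least 322-fold higher, ranging from 85.0 to 1448 between libraries. It stood at 0 to 0.721 in the mean of every other group. These include TNRC6A/B KO with siGL (0 reads) and with siTNRC6C (0.669 RPM), so the rise did not recur in the same genotype with siRNA. mir-548p and mir-3141 were called higher but not with replicate 3 as the only knockout library (adjusted p 0.31 and 0.152, n = 1 against 3), and mir-3141 not in a fit of only the compared groups (0.0605). With siGL in both genotypes neither stood far apart, mir-548p at 5.82 ± 2.56 in the knockout and 8.91 ± 1.97 in WT, and mir-3141 at 4.77 ± 1.31 and 4.34 ± 2.71. mir-3195, mir-4787 and mir-1234 fell, mir-3195 from 12150 ± 3467 to 172 ± 146. These 3 also stood low in WT cells given siGL, without the knockout, at 129 ± 44.3, 19.7 ± 7.86 and 31.0 ± 4.84 RPM against 12150, 575.5 and 1977 in WT. Arm ratios moved in 22 precursors, 7 towards the minor arm as in miR-30e (0.205 to 0.621) and 15 towards the major arm as in miR-25 (0.00416 to 0.000972), miR-19a and miR-331. With no filter the calls of miR-30e, miR-19a and miR-331 were lost (0.111, 0.177 and 0.113).

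With the control siRNA in both genotypes, TNRC6A/B KO again had more miR-181a-5p (17790 ± 1533 against 5023 ± 346 RPM) and less miR-4454 (119 ± 50.55 against 1906 ± 935), more miR-222-3p (1513 ± 46.4 against 330 ± 24.9, 4.59-fold) and miR-454-3p (312 against 84.3), and less miR-148a-5p and miR-210-5p (4.30-fold and 4.49-fold lower). For miR-210-5p this did not repeat the pair without siRNA, where it stood at 46.9 ± 5.40 in the knockout and 45.1 ± 6.44 in WT; with siGL it stood at 32.1 ± 5.10 in the knockout and 144 ± 58.0 in WT. limma called 56 higher and 108 lower, or 78 and 87 with median centring, which moved the median from -0.01 to 0.22. This pair of groups shares no library with the pair without siRNA. Over 739 entries the log2 differences of both pairs correlated at Pearson's r = 0.494; this r is across entries, which are not independent replicates. Rises called in both numbered 40 where 4.39 would be called if lists of 58 and 56 were independent, and falls called in both numbered 71 where 15.3 would be. The sign was opposite in 1 entry called in both. Both pairs take the spread of each entry from the same fit and compare the same genotypes. Their calls would thus not be independent, and the excess does not measure an effect of TNRC6 loss.

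Adding siTNRC6C to TNRC6A/B KO cells changed no entry by limma (0 of 739, with 34 at an unadjusted p under 0.05). voom also gave 0, no filter gave 3, and leaving out TNRC6A/B KO + siGL replicate 1, or a fit of only the compared groups, gave 1. Against WT with siGL the same cells had more miR-222-3p (2128 ± 77.9 against 330 ± 24.9, 6.45-fold), miR-454-3p (4.73-fold) and miR-181a-5p (21770 ± 4157, 4.33-fold), and less miR-4454 (23.0-fold lower), miR-210-5p (5.22-fold lower) and miR-7974 (802 ± 32.5 to 166 ± 41.4), with 59 higher and 123 lower, or 88 and 91 with median centring (median from -0.06 to 0.21). camera called 3 lists there, all up: the p53-induced miRNAs (4 of 5; 0.000897), the miR-181 family (4 of 8, 5 adjusted over the list alone; 0.000336) and the miR-21, miR-31, miR-155, miR-221 and miR-222 list (3 of 8, 4 adjusted over the list alone; 0.0049), with adjusted p = 0.0671, 0.123 and 0.0671 with an estimated correlation. In WT cells siTNRC6C raised miR-222-3p from 330 ± 24.9 to 570 ± 55.7 and lowered miR-196b-5p from 565 ± 64.2 to 301 ± 11.6 and miR-641 from 297 to 203, among 2 higher and 4 lower entries, or 3 and 3 with median centring (median from -0.07 to 0.10). The call of miR-641 was lost with median centring (adjusted p 0.277) or no filter (0.14), and that of miR-222-3p without WT + siTNRC6C replicate 1 (0.0541).

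WT cells given siGL differed from untreated WT cells in 19 entries. miR-210-5p rose from 45.1 ± 6.44 to 144 ± 58.0, miR-625-3p from 132 to 234 and miR-22-3p from 32530 ± 5739 to 56410 ± 6143, and miR-4787-5p, miR-10396b-3p and miR-4634 were 87.4-fold, 99.6-fold and 69.2-fold lower with siGL, among 11 rises and 8 falls. miR-4787-5p, miR-10396b-3p and miR-4634 also stood low in TNRC6A/B KO cells without siRNA, at 8.75, 0.716 and 15.6 RPM. For these entries the siRNA thus cannot be told apart from another difference between the libraries. The call of miR-22-3p was lost without WT replicates 1 or 2 or WT + siGL replicate 3 (adjusted p 0.0804, 0.109 and 0.095), and that of miR-625-3p with median centring (0.0546).

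**Figure D5:**
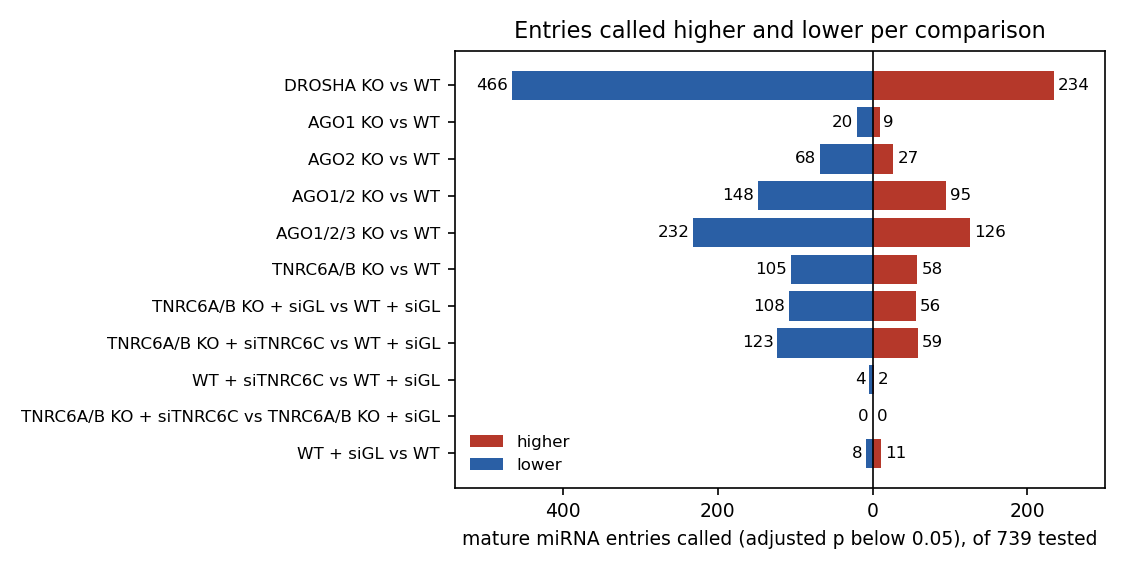
Number of mature entries called higher (right) and lower (left) by limma at an adjusted p under 0.05 (x axis) in 11 comparisons (y axis). DROSHA KO has most calls, 234 higher and 466 lower, and siTNRC6C in TNRC6A/B KO cells has 0.

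Of the fixed lists, 3 had too few tested members for a test. The chromosome 19 cluster summed to 1.77 ± 1.14 RPM in WT. miR-451a, which needs no Dicer, stood at 0.709 ± 0.321. The muscle, liver and neuron miRNAs had 2 tested members and summed to 1864 ± 118.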

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

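The tests chosen only after the result was seen were the arm ratios of TNRC6A/B KO set against the AGO series, those of arms chosen by their WT level, the look at which libraries the splits part, the tests of the largest falls in TNRC6A/B KO, and the unscaled reads of the mirtrons and of the miR-320 and miR-484 list.

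A test of the difference between effects picked out the interaction of AGO1 loss with AGO2 loss, in which 67 mature entries were called by limma. The effect of AGO1 loss on miR-22-5p was 2.385 higher on the log2 scale in cells without AGO2 than in cells with it (2.33 in AGO1/2 KO against AGO2 KO, and -0.05 in AGO1 KO against WT). For miR-642a-3p and miR-642b-5p, which share their reads, the difference was 2.108 (1.57 and -0.54). For miR-10b-5p it was -1.8 (-1.17 and 0.63), for miR-181b-5p -1.391 (-1.08 and 0.31) and for miR-500a-3p -1.351 (-1.64 and -0.29). Of 100 splits of the same 12 libraries, the real one included, 9 gave a count of 67 or more, the highest other calling 204. The other 8 all set libraries with and without AGO2 loss unevenly against each other, so the effect of AGO2 loss enters their counts and the share says nothing on chance for the interaction.

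The interaction of TNRC6A/B loss with siTNRC6C was picked out in the same way, with 2 entries called. For miR-196b-5p the effect of siTNRC6C was 0.8951 higher in TNRC6A/B KO (-0.01) than in WT cells (-0.90), a call lost with no filter (adjusted p 0.171) and with median centring (0.218). The other call was miR-1227-3p at -11.99 (-3.21 and 8.78), an entry named after its values were seen. miR-1227-3p had 0 reads over the untreated WT libraries and 34 over the DROSHA KO libraries, and groups other than WT let it through the filter. The log2 difference of an entry with few reads depends on the pseudocount, so the size of these values does not measure a fold. Of 100 splits 13 gave 2 or more calls, the highest other calling 146. The other 12 all set TNRC6A/B KO and WT libraries unevenly against each other, so the share says nothing on chance here either.

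Minor arms stood higher against major arms in AGO1/2/3 KO than in WT, with a median log2 change of 0.954 over 168 precursors. Lower depth of the AGO1/2/3 KO libraries was excluded as the whole cause, since thinning the WT reads to their mean total moved the median by -0.0173. Counting noise and shared reads were excluded too as the whole cause, for precursors with abundant arms only. Over 33 precursors with both arms at 100 RPM or more in WT and no shared reads the median change was 1.54 and 27 rose. Here the minor arm was the lower one in WT, a choice that can favour a rise, and no other knockout was measured this way. Over 35 chosen by their mean over all libraries, which lets in arms that rose, the median change was 1.17. With loss of AGO proteins as the hypothesis, the median was 0.615 in AGO1/2 KO, 0.0603 in AGO2 KO and -0.0483 in AGO1 KO, and where the labels name no loss of an AGO gene it was -0.19 in TNRC6A/B KO but 0.372 in DROSHA KO (94 of 168 up, and -1.99 over the 35 precursors). In DROSHA KO both arms fell in 131 of the 168 precursors, and ratios of arms near 0 reads depend on the pseudocount. Its median over all precursors thus cannot tell whether a higher median is particular to AGO loss. Over the 35 precursors the median was 1.08 in AGO1/2 KO, 0.263 in AGO2 KO, 0.00636 in AGO1 KO and -0.384 in TNRC6A/B KO. Whether a trait of the cell clones other than AGO loss contributes stays open, because the labels do not tell clones of a genotype apart.

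Of the 8 entries with the largest falls in TNRC6A/B KO, 7 stood under 100 RPM in WT cells with siGL. For these 7 a difference between libraries arose without the knockout: their median log2 difference between WT with siGL and WT without was -6.62, and 4 of them were called. The sign of this median was fixed by picking entries under 100 RPM in WT with siGL, but its size was not. Loss of TNRC6A and TNRC6B cannot be told apart from such a difference where both siGL groups stood near the floor. Over the 7, the knockout with siGL differed from WT with siGL by a median of 0.192. miR-4485-3p stood above the floor, at 27.4 RPM in the knockout with siGL and 13.15 in WT with siGL, so its fall did not recur there. The other entry, miR-4454, was 0.315 higher in WT with siGL than in WT, so the difference between these WT groups does not account for its fall. It differed by -3.97 between TNRC6A/B KO with siGL and WT with siGL, so its fall recurred in libraries not used for the first comparison. A trait of the TNRC6A/B KO cells other than the knockout cannot be told apart from it, as both comparisons use that genotype.

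Mirtron entries stood higher in DROSHA KO than in WT, where the smaller total of DROSHA KO libraries alone would raise any unchanged entry. Without scaling, all 12 mirtron entries had more reads in DROSHA KO (4908 against 929 in sum), with a median log2 difference of 3.77. Entries with 0 to 3 WT reads were let in by other groups, so this count and median were partly fixed in advance. The mirtrons miR-877-5p and miR-1226-3p passed the filter in WT. They had 943 against 557 and 2735 against 246 reads, which excludes scaling as the whole cause for them. Of the 12 entries 10 held 20 or more reads, which cannot exclude counting noise for entries chosen by their DROSHA KO level. For the miR-320 and miR-484 list as a whole scaling cannot be told apart from a rise. Its median unscaled difference was 0.566, and 4 of 6 entries had more reads, while the total fell by 3.69 on the log2 scale. miR-484, miR-320a-3p and miR-320b had 75410 against 16992, 45726 against 14422 and 3725 against 1952 reads. Scaling is thus not the whole cause for these members. miR-320c and miR-320d had fewer reads in DROSHA KO, at 463 against 496 and 183 against 235. How many reads each library was sequenced to is unknown, so a deeper sequencing of DROSHA KO libraries stays open for both lists.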

How the results depend on the processing

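Leaving out the DROSHA KO libraries, voom, and leaving out TNRC6A/B KO replicates 1 and 2 together were chosen only after the data were seen; the other alternatives were planned. Without replicates 1 and 2 TNRC6A/B KO has 1 library, and all spread comes from other groups. Over all alternatives, single mature entries and hairpins named in the text kept direction and side of the threshold in 3335 cases, lost their call in 143 and gained it in 33. Arm ratios kept both in 379 cases and lost the call in 33, and lists kept both in 1156, lost it in 40 and gained it in 1. The arm ratios of miR-181a and miR-130b in DROSHA KO against WT reversed with a pseudocount of 10, to 2.088 and 2.055. Without the DROSHA KO libraries the counts that moved by over 1.5 times were higher than as reported, except that of TNRC6A/B by siTNRC6C. Where no other reason is given below, the cause was not tested. The total of sequenced reads is unknown, and an entry with 0 reads in DROSHA KO libraries is bounded by their depth, 197912 mature reads at the lowest.

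Called mature entries moved by over 1.5 times as follows (as reported in brackets). Without the DROSHA KO libraries there were 58 in AGO1 KO (29), 186 in AGO2 KO (95), 277 in TNRC6A/B KO (163), 213 for AGO2 KO against AGO1 KO (112), 240 for AGO1/2 KO against AGO2 KO (152), 155 for AGO1 by AGO2 (67), 260 for TNRC6A/B KO against WT with siGL (164), 288 for TNRC6A/B KO with siTNRC6C against WT with siGL (182), 1 for TNRC6A/B by siTNRC6C (2) and 48 for WT with siGL against WT (19). With only the compared groups these were, in AGO1 KO, AGO2 KO, AGO2 KO against AGO1 KO, AGO1/2 KO against AGO2 KO, AGO1 by AGO2, both siGL groups, TNRC6A/B KO with siTNRC6C against WT with siGL, and WT with siGL against WT, 127, 257, 297, 236, 199, 280, 305 and 85, with 1 for siTNRC6C in TNRC6A/B KO (0) and 34 for siTNRC6C in WT (6). With a pseudocount of 10 there were 73 in AGO1 KO, 211 in AGO2 KO, 372 in AGO1/2 KO (243), 288 in TNRC6A/B KO, 240 for AGO2 KO against AGO1 KO, 256 for AGO1/2 KO against AGO2 KO, 172 for AGO1 by AGO2, 287 for TNRC6A/B KO against WT with siGL, 315 for TNRC6A/B KO with siTNRC6C against WT with siGL, 56 for WT with siGL against WT and 19 for siTNRC6C in WT. voom gave 77, 238, 405, 334, 257, 275, 177, 308, 329, 60 and 15 for these same comparisons in this order. A filter of 100 RPM, which tests fewer entries, gave 357 in DROSHA KO (700), 153 in AGO1/2 KO, 200 in AGO1/2/3 KO (358), 106 in TNRC6A/B KO, 74 for AGO2 KO against AGO1 KO, 96 for TNRC6A/B KO against WT with siGL, 103 for TNRC6A/B KO with siTNRC6C against WT with siGL, 3 for siTNRC6C in WT and 1 for TNRC6A/B by siTNRC6C. No filter, which tests more entries, gave 1073 in DROSHA KO, 13 in AGO1 KO, 35 for AGO1 by AGO2 and 3 for siTNRC6C in TNRC6A/B KO. Median centring and a pseudocount of 0.25 each gave 1 for TNRC6A/B by siTNRC6C.

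Called hairpins without the DROSHA KO libraries were 25 in AGO1 KO (4), 107 in AGO2 KO (29), 249 in AGO1/2 KO (30 higher and 95 lower as reported), 357 in AGO1/2/3 KO (195) and 222 in TNRC6A/B KO (107). With only the compared groups they were 39, 104, 204 and 293 in the AGO series. A pseudocount of 10 gave 8, 49, 226, 324, 1183 in DROSHA KO (771) and 363 in TNRC6A/B KO, and voom gave 16, 84, 271, 383, 1169 and 403. A filter of 100 RPM gave 438 in DROSHA KO, a pseudocount of 0.25 gave 195 in TNRC6A/B KO, and median centring gave 0 in AGO1 KO, 16 in AGO2 KO and 225 in TNRC6A/B KO. With limma, the 0 in AGO1 KO with centring stands beside 4 as reported.

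Called arm ratios without the DROSHA KO libraries were 4 in AGO1 KO (0), 58 in AGO2 KO (22), 88 in AGO1/2 KO (47), 110 in AGO1/2/3 KO (50) and 63 in TNRC6A/B KO (22). With only the compared groups they were 56, 89 and 103 in AGO2, AGO1/2 and AGO1/2/3 KO and 41 in TNRC6A/B KO. A pseudocount of 10 gave 9, 65, 105 and 126 in the AGO series, 145 in DROSHA KO (81) and 79 in TNRC6A/B KO, and one of 0.25 gave 91 in AGO1/2/3 KO. A filter of 100 RPM gave 36 in DROSHA KO, 14 in AGO2 KO, 28 in AGO1/2 KO and 24 in AGO1/2/3 KO, and no filter gave 197 in DROSHA KO, 5 in AGO2 KO and 10 in TNRC6A/B KO. With an estimated correlation, camera called 1 list in DROSHA KO (15), 2 in AGO1 KO (5) and 0 in AGO1/2/3 KO (3), TNRC6A/B KO (7) and TNRC6A/B KO with siTNRC6C against WT with siGL (3); the latter 3 had 8, 7 and 5 lists at an unadjusted p under 0.05 at the preset correlation, and fry, which does not compare a list with the other entries, called 17, 7 and 5. The correlation between the TNRC6A/B comparisons (0.494) was 0.5347 without the DROSHA KO libraries, 0.5608 with a filter of 100 RPM and 0.7043 with a pseudocount of 10.

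Leaving out 1 library at a time moved these counts: mature entries in AGO1 KO to 11 (without WT replicate 1) to 16 (without WT replicate 2), siTNRC6C in TNRC6A/B KO to 0 to 1 (without TNRC6A/B KO with siGL replicate 1), WT with siGL against WT to 11 (without WT replicate 1) to 19, hairpins in AGO1 KO to 2 (without WT replicate 1) to 6 (without AGO1 KO replicate 2), arm ratios in TNRC6A/B KO to 14 (without WT replicate 2) to 19 (without WT replicate 3), and the correlation to 0.4341 (without TNRC6A/B KO replicate 3) to 0.502 (without TNRC6A/B KO replicate 2). With 1 library left out at a time, all other counts of calls stayed within 1.5 times of those reported. Blocking by replicate number moved no count by over 1.5 times, and of the single entries named it ended 1 call, that of miR-30a-3p in AGO1/2/3 KO (adjusted p 0.0537). The pairing by number gave a mean correlation of 0.0737 over 165 pairs of libraries with the same number, and 17 of 33 libraries correlated best with their own number.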

Other observations

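The splits of libraries reported here were planned, and the values per group and library were looked at only after the data were seen.

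Reads on hairpin entries per read on mature entries averaged 0.429 ± 0.0093 in WT (SD, n = 3), 0.427 ± 0.0107 in AGO1 KO, 0.472 ± 0.0070 in AGO2 KO, 0.508 ± 0.0184 in AGO1/2 KO, 0.580 ± 0.0155 in AGO1/2/3 KO, 0.352 ± 0.0235 in TNRC6A/B KO and 0.408 ± 0.0150 in DROSHA KO. The sum of the blood cell miRNAs was 280 ± 65.9 RPM in WT and 1972 ± 161 in AGO1/2/3 KO, with 2 of 4 members called higher by limma (camera adjusted p = 0.1097). The sum of the miR-183 cluster was 23660 ± 1023 RPM in WT and 9408 ± 806 in AGO1/2/3 KO, with 2 of 4 members called lower (0.315). The muscle, liver and neuron miRNAs summed to 160 ± 16.4 RPM in AGO1/2/3 KO and 3.24 ± 2.82 in DROSHA KO.

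TNRC6A/B KO replicates 1 and 2 had 11397 and 18860 RPM on the 1393 hairpins that averaged under 10 RPM in WT, against 4115 in replicate 3; the DROSHA KO libraries had 57490 to 60161.

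With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For mature entries the real count, the highest other count and the number of splits with as large a count were 700, 41 and 1 in DROSHA KO, 29, 2 and 1 in AGO1 KO, 95, 1 and 1 in AGO2 KO, 243, 2 and 1 in AGO1/2 KO, 358, 3 and 1 in AGO1/2/3 KO, and 163, 1 and 1 in TNRC6A/B KO. They were 112, 1 and 1 for AGO2 KO against AGO1 KO, 152, 5 and 1 for AGO1/2 KO against AGO2 KO, and 227, 17 and 1 for AGO1/2/3 KO against AGO1/2 KO. Among groups with siRNA they were 164, 0 and 1 for TNRC6A/B KO against WT with siGL, 6, 1 and 1 for siTNRC6C in WT, 0, 0 and 10 for siTNRC6C in TNRC6A/B KO (34 entries at an unadjusted p under 0.05 by limma, 0 calls by voom), 182, 2 and 1 for TNRC6A/B KO with siTNRC6C against WT with siGL, and 19, 1 and 1 for siGL in WT.

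For hairpins the same numbers were 771, 26 and 1 in DROSHA KO, 4, 0 and 1 in AGO1 KO, 29, 2 and 1 in AGO2 KO, 195, 5 and 1 in AGO1/2/3 KO and 107, 35 and 1 in TNRC6A/B KO, and in AGO1/2 KO no hairpin was called in the other splits by limma, with 1 split as large. For arm ratios they were 81, 18 and 1 in DROSHA KO, 0, 1 and 10 in AGO1 KO, 22, 0 and 1 in AGO2 KO, 47, 1 and 1 in AGO1/2 KO, 50, 2 and 1 in AGO1/2/3 KO and 22, 1 and 1 in TNRC6A/B KO. For lists by camera they were 15, 12 and 1 in DROSHA KO, 5, 2 and 1 in AGO1 KO, 0, 0 and 10 in AGO2 KO, 0, 1 and 10 in AGO1/2 KO, 3, 1 and 1 in AGO1/2/3 KO, 7, 5 and 1 in TNRC6A/B KO, and 3, 3 and 4 in TNRC6A/B KO with siTNRC6C against WT with siGL.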
